A study of Arabidopsis thaliana with 11 samples.

How the data were processed

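RNA was sequenced from whole Arabidopsis thaliana plants at 3 weeks of age. Per the labels, they had spent 21 days on the Phenoscope, an automated platform that controls the water of each pot, under control watering or drought stress. Total RNA was extracted with a Qiagen plant kit and libraries were made for the Illumina HiSeq2000, per the labels' protocols. Col-0 is the reference accession of the species and Cvi-0 comes from the Cape Verde Islands; they differ at many sites in transcribed sequence, so a read that covers such a site can be assigned to the Col or the Cvi allele. The 11 libraries fall into 5 groups: F1 hybrid plants (labelled Col x Cvi) under control (n = 3) and drought (n = 3), pools of equal amounts of cDNA of the parents under control (n = 2) and drought (n = 2), and a plant of the other cross direction under control (n = 1). Each F1 library is 1 plant. The labels call the libraries of a group separate samples, and nothing states how many plants entered a pool or whether pools share them. So p-values measure only the spread between these samples, which for the pools may be technical. The spread is estimated over all replicated groups at once, so tests among F1 plants also draw on the spread of the pools.

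The authors deposited 1 table per library. Per the file headers, it holds a count of reads per gene or transposable element, a count of reads called inconsistent, which the header does not define, and the reads of each allele per gene and per polymorphic site. Genes and sites are numbered on build TAIR 10, per the submitters' processing notes; the aligner and its settings are not given in the sources used here. The deposited counts of reads per gene are whole numbers. The allele reads deposited by the authors are estimated counts: a read that covers several sites is shared among them, so that a site can hold a fraction of a read. From the values, they are stored at reduced precision (16-bit floating point), and at most 50 sites are listed for any gene (645 genes reach that number). This format turns a very large number into infinity; 2 genes, AT1G72600 and GER1, were infinite in some library and were left out of the allele analyses. All 270468 site entries listed carry the base of the Col-0 reference assembly, so coordinates are given on that assembly, counted from 1 at the start of each chromosome. Gene names came from the NCBI RefSeq annotation, which matched 32835 of the 33323 genes listed. The tables list no organelle genes, so a planned look at maternally inherited transcripts was not made.

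Reads per library assigned to genes ranged from 22352238 to 26260523. Because a read in an exon shared by overlapping genes cannot be placed, allele reads were summed per gene over the sites in exons of exactly 1 gene: of the 270468 entries, 13837 lay in exons shared by genes and 4373 outside exons. A site can be entered more than once; counted once per gene, 251536 sites in 26484 genes were kept. These sums, called site reads here, were 3283119 to 3828136 per library and were rounded to whole numbers, as count models need. Genes with a mean of at least 20 site reads per library were tested, 10293 in all. The sum of both alleles measured a gene's level. The log2 of Cvi over Col reads measured its allelic ratio, where 0 is an equal share and positive values mean more Cvi reads. After the data were examined, levels were also computed from the deposited count of all reads per gene (18867 genes), a column that had not been foreseen. It includes reads without a polymorphic site and has no allele information.

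Levels were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM library factors and 1 model of the 4 replicated groups (10 libraries). Ratios were tested in the same way, with the Col and the Cvi reads of each library as 2 columns, a term per library, and TMM factors for the columns. These factors centre each column, so a ratio is measured relative to the bulk of genes. Without centring the median log2 ratio of a library lay between -0.27 and -0.08, so splits of higher against lower ratios are also given without it. Calls are at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, and every adjusted p printed here comes from edgeR's quasi-likelihood test with that adjustment unless another tool is named. Where counts at an unadjusted p under 0.05 are given, chance alone would give a share of about 0.05 of all tested genes. Errors of log2 values are standard errors of the fit, and errors of CPM (counts scaled to a common library size) and percentages are SD over libraries. Gene lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists with at least 5 measured genes. The same lists were tested with the correlation estimated from the data and with fry, which asks whether a list's genes move, on balance, one way and does not compare them with other genes.

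The comparisons, tests and lists and most alternatives were fixed before the data were examined. The lists covered response to drought and abscisic acid (ABA), aquaporins, cell wall expansion, photosynthesis, glucosinolates, flavonoids, the circadian clock, flowering, salicylate defence, NLR immune receptors, heat shock, cold and touch, markers of roots, of flowers and seeds and of guard cells, reference genes, and loci described as differing between Col and Cvi. Genes are named by a rule fixed at the same time. For levels, it took the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean count of at least 50 per library and no overlap between the CPM of both groups. For ratios, it took the 10 largest and 10 smallest values among called genes with at least 2 sites and 10 reads of the rarer allele in every F1 library (pool library for parental ratios). The text names fewer in rank order and may name any measured member of a list; where others are named, it says so.

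The tests were run on simulated data made from the means of the 10293 genes, with 100 genes changed by a log2 of 1 and 100 by a log2 of 2. For the effect of drought on F1 levels, 67% and 98% of them were recovered, with 14 false calls (7.82% of all calls). For the F1 ratio under control the shares were 69% and 98% (13 false calls, 7.22%). For the change of that ratio with drought they were 47% and 84% (8 false calls, 5.76%). For the parental minus the F1 ratio under control they were 41% and 87% (4 false calls, 3.03%). The simulation gave each gene the same spread in pools and F1 plants. It therefore cannot show how many false calls arise if the pools vary less than the plants.

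To find genes that share reads with near-identical copies, every 30-base word of a gene's exons was looked up in the whole genome. A gene with at least 10% of its words present elsewhere is called repeated here and its values are uncertain, since the counting could have split its reads. Alternatives were DESeq2 1.42.0, no centring of the ratio, no minimum count or a mean of at least 100, sites at least 100 bp apart, the deepest site of each gene, all sites in the gene span, sites where the rarer allele is under 1% left out, the replicate number as a block, only the compared groups in the model, the other cross direction joined to the F1 control plants, each library left out in turn and, added later, the deposited allele reads per gene. Splits of the 6 F1 plants into groups of 3 gave 10 arrangements and swaps of the allele labels 32, the real one included in each. Other computations and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.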

Results

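Gene expression and its allelic balance were measured in hybrids of the accessions Col-0 and Cvi-0, and in pools of their parents, with and without drought. The 11 libraries comprised 3 F1 plants under control, 3 under drought, 2 parental pools under each condition and 1 control plant of the other cross direction. Between 22352238 and 26260523 reads per library were assigned to genes, and 3283119 to 3828136 of them could be read at polymorphic exon sites. Cvi reads made up 44.4% ± 0.173 of site reads in the F1 plants under control (SD, n = 3) and 45.0% ± 0.290 under drought (n = 3). They made up 46.3% ± 0.414 in the control pools (n = 2), 48.6% ± 0.440 in the drought pools (n = 2) and 44.8% in the plant of the other cross direction. Transposable elements took 0.807 to 0.944% of all reads, and the 10 most abundant genes 15.3 to 18.5% of all reads assigned to genes. Libraries of the same group differed by more than counting noise, with a chi-square of 3.54 to 18.16 per degree of freedom over genes, so none was a copy of another. F1 control plant 3 and F1 drought plant 1 stood furthest from the others: their log2 CPM of site reads correlated with those of the other libraries at 0.919 to 0.968 and 0.919 to 0.965. Their 10 most abundant genes took 15.3% and 15.4% of all reads assigned to genes.

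The series asks how gene expression and its allele balance respond to drought in the hybrids. VSP2, a vegetative storage protein and jasmonate response gene (chromosome 5, 8500468 to 8502224), went from 8.44 ± 2.49 to 93.9 ± 35.2 CPM of all reads (SD, n = 3 plants each). That is a log2 change of 3.47 ± 0.30 in site reads (adjusted p = 0.000288) and 3.48 ± 0.31 in all reads. LTP3, a lipid transfer protein of the drought and ABA list (chromosome 5, 23928954 to 23929816), rose by a log2 of 4.16 in site reads (adjusted p = 0.00163) and 3.22 ± 0.27 in all reads. Its neighbour LTP4 went from 0.256 ± 0.208 to 11.3 ± 4.35 CPM of all reads. BAM5, a beta-amylase, rose by 3.12 ± 0.33 and 2.86 ± 0.33 in site and all reads, the expansin EXPA16 by 2.30 and 2.54, the storage protein VSP1 by 2.28 and 2.48, and RD20, a calcium-binding lipid droplet protein, by 2.08 and 2.06. The other large rises were smaller in all reads: RGF9 and PSK3, precursors of signalling peptides, rose by 3.33 and 2.89 in site reads but by 0.97 and 0.88 in all reads. LON2, a peroxisomal protease, and NHL3 rose by 1.93 and 1.80 in site reads and stood at 0.10 and 0.34 in all reads, which did not pass the test. Of the 10 largest falls, 3 passed with both kinds of read: AT3G47836 (-1.89 in site and -1.34 in all reads), the polyamine oxidase PAO4 (-1.84 and -0.59) and AT1G53790 (-1.83 and -1.21). AT2G22360, ILR3, AT1G29530, GRP3S, GRP-3, AT1G52220 and PGLCT fell in site reads, by -2.16 for AT2G22360 to -1.78 for PGLCT, and had log2 values from -1.82 for GRP3S to -0.14 for PGLCT in all reads, without passing the test there.

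Genes of the drought and ABA list rose together. In site reads 11 of its 22 measured members rose and none fell, and adjusted over the list alone 14 rose and 1 fell. In all reads 15 of 36 rose and none fell, and adjusted over the list alone 21 rose. COR15A, which protects chloroplast membranes (chromosome 2, 17710441 to 17712330), went from 47.6 ± 1.66 to 132 ± 21.1 CPM of all reads (n = 3), a log2 of 1.47 ± 0.13 in all reads and 1.72 ± 0.19 in site reads (adjusted p = 0.00145). KIN1 and KIN2 rose by 1.58 and 1.29 in site reads, RD29A by 0.93 ± 0.17, COR47 by 1.27 (0.53 in all reads), the galactinol synthase GOLS1 by 1.43, the transcription factor ABF3 by 1.21 and the proline synthesis gene P5CS1 by 1.005. GOLS2, LEA4-5, COR15B and ATHB7, which were not measured at sites, rose in all reads by 2.82, 2.01, 1.198 and 0.76. The list's camera adjusted p was 2.42e-09 in site reads (adjusted p = 0.0171 with an estimated correlation, 0.000194 by fry) and 1.11e-13 in all reads (adjusted p = 0.0371 with an estimated correlation).

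**Figure D1:**
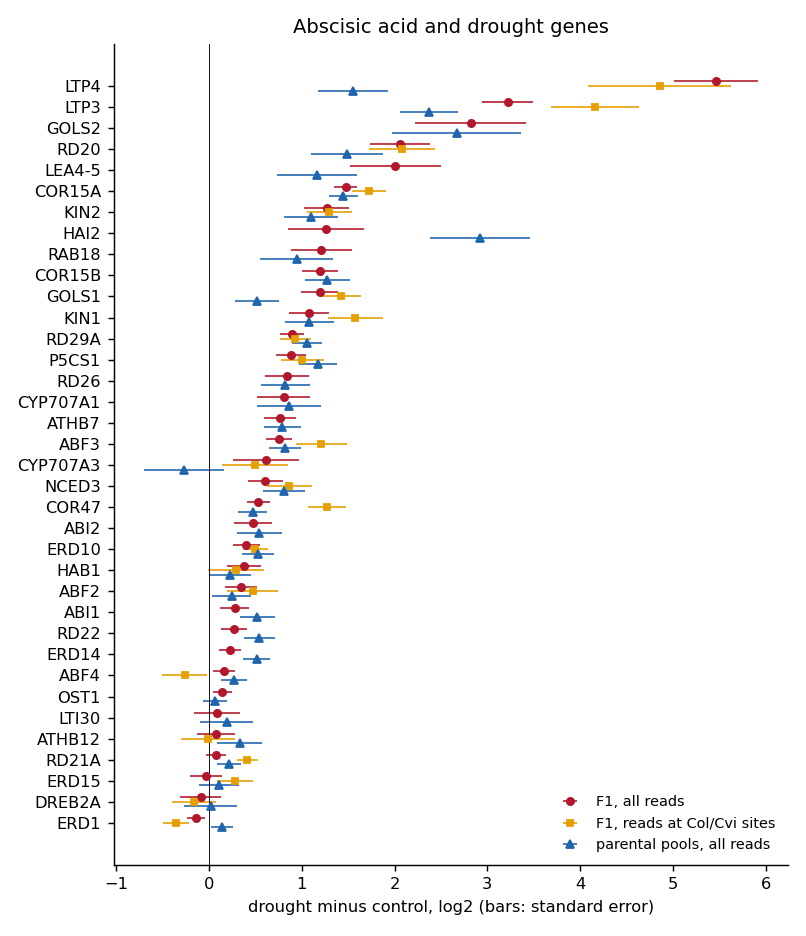
Log2 change with drought (x axis, drought minus control) of each measured gene of the drought and ABA list (y axis, ordered by the F1 value in all reads), for F1 plants from all reads (circles) and site reads (squares), n = 3 plants per condition, and for parental pools from all reads (triangles), n = 2 per condition; bars are standard errors. In F1 all reads 15 of 36 genes passed the test, all to the right of 0, from COR47 at 0.53 upward; the square of LTP4 is a fitted value, since F1 control libraries held hardly any site reads of it.

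Of 4 further lists called by camera in site reads, all lost that call with an estimated correlation. Glucosinolate genes, which make defence compounds of the cabbage family, were higher: 3 of 23 rose (9 adjusted over the list alone), and the camera adjusted p was 3.97e-05 (adjusted p = 0.199 with an estimated correlation). BCAT4 rose by 1.79 in site reads and 0.65 in all reads, while MAM3 (0.69) and CYP83A1 (0.63) rose in site reads and stood at 0.25 and 0.22 in all reads; AOP2 (0.49) and GGP1 (0.54) rose in all reads. Flavonoid genes, which make anthocyanin pigments, had 2 of 9 members up (3 adjusted over the list alone; camera adjusted p = 0.00637, adjusted p = 0.203 with an estimated correlation). These were UGT79B1 (1.55 ± 0.33 in site and 1.297 ± 0.28 in all reads) and LDOX (0.84 ± 0.20 and 0.85 ± 0.15), with DFR at 0.59 in all reads. Of cell wall expansion genes 1 of 11 fell (5 adjusted over the list alone; camera adjusted p = 0.00639, adjusted p = 0.199 with an estimated correlation). That gene was XTH8, at -1.62 in site reads and -0.26 in all reads, where it did not pass, while EXPA10 rose by 0.58 in all reads. Of 7 NLR receptors none passed the test of single genes (3 fell adjusted over the list alone; camera adjusted p = 0.0118, adjusted p = 0.303 with an estimated correlation). In all reads camera also called the glucosinolate, heat shock, salicylate and NLR lists, with estimated-correlation adjusted p = 0.441, 0.229, 0.441 and 0.517.

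Among 12 aquaporins TIP2;1 fell by -0.66 ± 0.16 in site and -0.68 ± 0.14 in all reads, and 3 rose and 3 fell adjusted over the list alone. The other called member, PIP2;2, is repeated and went up by 1.301 in site reads but stood at -0.52 in all reads. In all reads PIP1;1 (0.51), PIP1;2 (0.59) and PIP2;5 (0.53) rose too. Of 27 photosynthesis genes 3 rose and 1 fell in site reads (7 and 3 adjusted over the list alone). PSBP1 went from 0.65 in site reads to -0.34 in all reads, PETE1 (0.70) and PSBO2 (-0.75) stood at 0.10 and -0.20 in all reads, and only PSAE1 (0.71) rose there. The clock gene PRR7 (-0.81) and the reference gene SAND (-1.16) fell in site reads and stood at -0.18 and -0.16 in all reads. They were the single calls among 6 genes of each list (1 fell, and 1 rose and 1 fell, adjusted over the list alone). HSP70 rose by 0.80 in all reads, 1 of 5 heat shock genes there (3 adjusted over the list alone). No gene passed among 8 flowering, 4 salicylate, 4 guard cell, 2 cold and touch, 1 root and 1 heat shock gene or 7 loci described as differing between Col and Cvi. Adjusted over the list alone, 1 salicylate and 1 root gene fell, 1 guard cell gene rose, and 1 described locus rose and 1 fell. None of the flower and seed markers was measured.

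In all, 555 of 10293 genes passed in site reads, 275 higher and 280 lower under drought, and 659 of 18867 in all reads, 359 higher and 300 lower. With only the F1 groups in the model, and so without the spread of the pools, 203 passed in site reads. Only 167 of the 555 were also called in the same direction from all reads (93 higher, 74 lower), although 508 had the same sign; their median size was 0.96 in site and 0.34 in all reads. In site reads leaving out F1 control plant 2 left 147 calls, drought plant 3 left 183, drought plant 1 left 274 and control plant 3 left 333, against 879 without drought plant 2. Of the 43 genes named as called from site reads, 20 stayed called whichever plant was left out, among them VSP2, LTP3, BAM5, COR15A and RD29A. The call was lost by 20 of the 43 without F1 control plant 2, 16 without drought plant 3, 14 without drought plant 1, 12 without control plant 3, 5 without control plant 1 and 1 without drought plant 2. In all reads 139 calls were left without F1 control plant 2, 254 without control plant 3, 302 without drought plant 3, 379 without drought plant 1 and 417 without control plant 1. There 14 of 38 named genes stayed called throughout, and 24 lost the call without control plant 2, 18 without control plant 3, 16 without drought plant 3, 10 without drought plant 1, 9 without control plant 1 and 6 without drought plant 2.

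**Figure D2:**
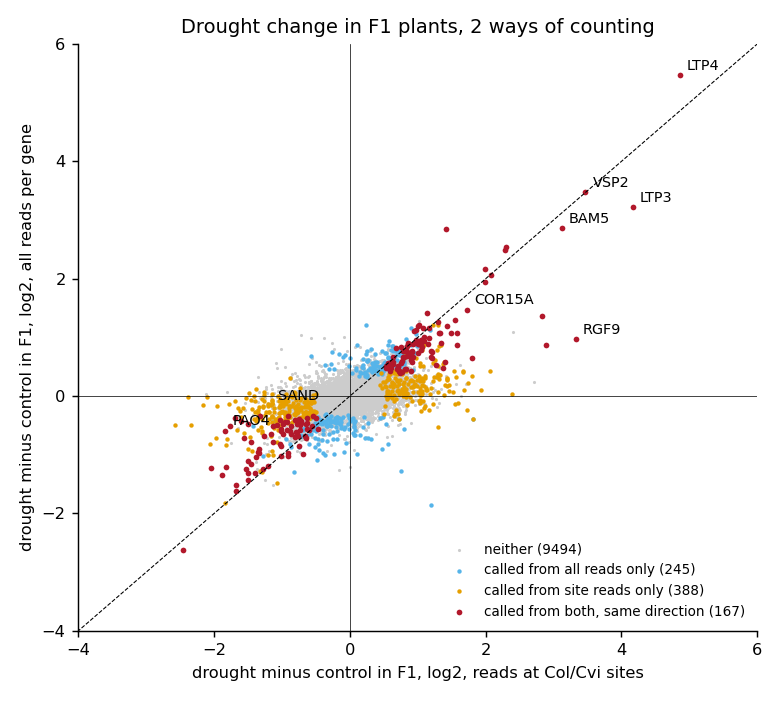
Log2 change with drought in F1 plants from site reads (x axis) against all reads of the gene (y axis), 1 point per gene measured both ways, n = 3 plants per condition; the dashed line marks equal values. Of the 167 genes called both ways some lie near the line (VSP2, BAM5) and others have smaller values in all reads (RGF9, 3.33 and 0.97), while the 388 called from site reads only include genes close to 0 in all reads (SAND, -1.16 and -0.16).

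In the parental pools 4 genes passed in site reads, and all 4 passed in all reads. VSP2 rose by 2.497 ± 0.34 (adjusted p = 0.0323), COR15A by 1.48 ± 0.23 (adjusted p = 0.0477) and the vacuolar aquaporin TIP2;2 by 1.16 ± 0.18 (adjusted p = 0.0477). ERD5, a proline dehydrogenase (chromosome 3, 12448636 to 12451556), fell by -1.62 ± 0.22 (adjusted p = 0.0323; n = 2 pools each). The same genes changed in the F1 plants, TIP2;2 by 0.90 ± 0.14 and ERD5 by -1.01 ± 0.18. All reads called 17 genes in the pools, 13 higher and 4 lower, with LTP3 at 2.37 ± 0.31 and RD29A at 1.05 ± 0.16. The drought and ABA list was higher here as well, with 1 of 22 genes called (10 up adjusted over the list alone; camera adjusted p = 1.14e-14, adjusted p = 0.00495 with an estimated correlation, 0.00155 by fry). Camera also called the flavonoid and glucosinolate lists (adjusted p = 0.00501 for each; adjusted p = 0.350 and 0.460 with an estimated correlation). Of the 555 genes called in F1 site reads, 372 (67.0%) had the same sign in the pools, with a median change of 0.14 in the F1 direction. A test of whether drought acted differently in F1 plants and pools called 0 genes with edgeR (815 at an unadjusted p under 0.05, 22 by DESeq2), and 0 in all reads (1134 at an unadjusted p under 0.05). In site reads the pools gave 0 calls without control pool 1, control pool 2 or drought pool 4 and 2 without drought pool 3. In all reads they gave 0, 1, 10 and 12 without control pools 1 and 2 and drought pools 4 and 3, so no named gene stayed called throughout. The test of the difference gave 53 calls without F1 drought plant 2 (13 in all reads), and in all reads 1 without control pool 1 and 2 without drought pool 4.

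F1 plants were then compared with the pools at the level of total expression, which asks where a hybrid departs from the average of its parents. Under control 33 genes differed, 5 higher and 28 lower in F1 (7 with the plant of the other cross direction joined to the F1 controls, 1 higher and 6 lower). PCC1, a pathogen response gene, stood at -2.79 ± 0.43 (n = 3 F1 plants and 2 pools; repeated), LURP1, another pathogen response gene, at -2.57 ± 0.48, and AT5G03350 at -2.35 ± 0.29. The anthocyanin glycosyltransferase UGT79B1 stood at -2.24 ± 0.34, and the wall-associated kinases WAK1 and WAK4 at -2.17 ± 0.26 (repeated) and -1.93 ± 0.23. The receptor-like protein RLP34 stood at -2.10 ± 0.22 (repeated), the ankyrin protein ANK at -2.08 ± 0.26. ACD6, an ankyrin protein of salicylate defence (chromosome 4, 8294165 to 8299195), stood at -1.97 ± 0.30, and LDOX, the anthocyanidin synthase (chromosome 4, 12004726 to 12006209), at -1.94 ± 0.21 (adjusted p = 0.00144). Higher in F1 were the terpene synthase TPS03 at 2.54 ± 0.32 (adjusted p = 0.00301), AT5G38100 at 1.32 ± 0.23 and the glycolate oxidase GOX2 at 0.93 ± 0.15, which stood at 0.10 in all reads without passing. Of the 33 genes, 29 were called in the same direction from all reads, which called 114 genes (10 higher, 104 lower).

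Of the flavonoid genes, camera called the list lower in F1 plants than in pools, a call lost with an estimated correlation in both kinds of reads. Under control 3 of 9 measured at sites were lower and none higher, LDOX, UGT79B1 and the glutathione transferase TT19 (-1.20 ± 0.20); adjusted over the list alone 6 were lower. In all reads 7 of 17 were lower (10 adjusted over the list alone), with 5MAT at -2.17, DFR at -1.82, TT8 at -1.58 and F3PH at -1.36. The camera adjusted p was 3.32e-08 in site reads (adjusted p = 0.0699 with an estimated correlation, 0.00762 by fry) and 4.24e-14 in all reads (adjusted p = 0.121 with an estimated correlation). Salicylate defence genes were lower in all reads by camera (adjusted p = 0.0105; adjusted p = 0.428 with an estimated correlation), with 1 of 11 called, WRKY70 at -1.87, and 1 higher and 6 lower adjusted over the list alone. PR1, the classical salicylate marker, had a site-read value of -4.50 ± 0.96 and did not pass (adjusted p = 0.0918); it turned to 1.56 with the plant of the other cross direction joined to the F1 controls. Camera called 3 more lists under control at an adjusted p of 0.0242 for drought and ABA genes (lower), 0.0305 for photosynthesis (higher) and 0.0305 for the described loci (higher), with adjusted p = 0.272, 0.475 and 0.414 with an estimated correlation. Under drought 27 genes differed, 5 higher and 22 lower, with TPS03 at 2.53 ± 0.31 and PCC1 at -3.72 ± 0.47 (repeated), RLP34 at -2.31 (repeated), AT5G03350 at -2.20, AT1G35710 at -2.11, ACD6 at -1.96 and LDOX at -1.75. AT5G38100 (1.44), AT2G19680 (1.34), AT2G43550 (1.19) and the ascorbate peroxidase APX1 (0.90) were also higher. Both conditions shared 20 genes, all in the same direction, against 0.0623 for independent lists of these sizes. The flavonoid list had 2 of 9 genes lower (6 adjusted over the list alone; camera adjusted p = 1.87e-05, adjusted p = 0.179 with an estimated correlation, 0.0149 by fry). Camera called the cell wall and NLR lists lower (adjusted p = 0.0122 each) and the glucosinolate list higher (0.0204), with adjusted p = 0.261, 0.428 and 0.561 with an estimated correlation. Under control 4 calls were left without control pool 2, 8 without control pool 1, 12 without F1 control plant 2 and 21 without F1 control plant 1 or 3 (in all reads 32 without either pool and 52 without plant 2). Of 14 genes named there 12 lost the call without control pool 2 (all but RLP34 and LDOX), 8 without control pool 1, 7 without F1 control plant 2, 4 without plant 1 and 3 without plant 3, and in all reads LDOX, DFR, 5MAT and TPS03 stayed called throughout. Under drought 4 were left without drought pool 3 or F1 drought plant 3 and 8 without drought plant 1, against 221 without drought plant 2. RLP34, AT1G35710 and LDOX stayed called throughout, and without drought pool 3 they were the only named genes called.

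Within F1 plants both alleles share the same cells, so the ratio of their reads compares the alleles in a common background. Both conditions together, ratios of 5414 of 10293 genes (52.6%) differed from the bulk, 2647 toward Cvi and 2767 toward Col (1142 and 4298 without centring), and in 1677 of them by a log2 of at least 1. The median size among called genes was 0.69. Repeated genes made up 7.68% of them, against 5.48% of all tested genes (called against the remaining tested genes, Fisher's exact test, p = 4.4e-26, two-sided). ESM1, an epithiospecifier modifier (chromosome 3, 4729399 to 4731847; repeated), had 1.17% ± 0.0669 Cvi reads under control (n = 3). Its log2 Cvi/Col over both conditions was -6.11 ± 0.07. ESP, the epithiospecifier protein that directs glucosinolates toward nitriles, had 85.4% ± 1.01 Cvi reads under control and a log2 of 2.90 ± 0.08 over both conditions. Other alleles expressed mainly from Cvi were AT1G67105, a noncoding RNA (chromosome 1, 25057479 to 25058264; log2 5.85 ± 0.13), the aldolase FBA7 (3.93 ± 0.08; chromosome 4, 13388290 to 13390862), the thionin THI2.2 (3.66 ± 0.13) and the ribosomal protein gene AT4G18100 (3.44). They were followed by GOX2 (3.25), the hydroperoxide lyase HPL1 (3.20), CYP71B19 (3.17; repeated), RAN2 (3.17) and the tubulin TUA6 (3.01; repeated). Those expressed mainly from Col were AT4G13495 (-5.98), the dioxygenase gene AT2G25450 (-5.55), KIN2 (-5.46), AT4G23670 (-5.13), ACL (-4.64), LIL3:1 (-4.55), the chloroplast RNA-binding protein CP29 (-4.49), CYP79F2 of glucosinolate synthesis (-4.42) and AT3G13410 (-3.94). The KIN2 ratio turned to 1.05 when sites with under 1% of the rarer allele were left out, so its direction rests on such sites. At the deepest sites of LIL3:1 and AT3G13410, Cvi reads were 0.035% and 0% over all F1 libraries. In all pool libraries they were 0% and 0.028%. A wrongly listed base and a silent allele cannot be distinguished at such a site. For the other genes named toward Col, KIN2 apart, the F1 share at the deepest site was 1.91 to 3.21%.

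The splits of the fixed lists depend on the centring, so each is followed by the split without it. All 12 aquaporins were called, 10 toward Cvi and 2 toward Col (5 and 2 without centring; PIP2;1 at 1.36 ± 0.06 and TIP1;2, AT3G26520, at -2.699 ± 0.07). Of 23 glucosinolate genes 11 favoured Cvi and 9 Col (4 and 10), with the chain elongation genes MAM3 at 1.65 ± 0.08 and MAM1 at -1.78 ± 0.07, the regulator MYB34 at -2.71 ± 0.16 and BCAT4, at a single site, at -2.61 ± 0.19. All 7 NLR receptors were called, 1 toward Cvi and 6 toward Col (0 and 6), but RPP1 (-2.76) and RPP5 (-2.06) are repeated, and RPP5 turned to 0.18 at its deepest site and 0.27 with rare-allele sites left out. At the deepest site, over all F1 libraries, the Cvi share was 61.3% in RPP4, 50.7% in SNC1 and 49.7% in ZAR1. It was 41.6% in RPP8, 39.4% in RPP13 and 0.37% in RPP1, so the lean toward Col was not shared by all of them there. Photosynthesis genes split 18 toward Cvi and 5 toward Col of 27, but 6 and 12 without centring, with PSAD1 at -3.31 ± 0.10 and LHCB1.1 (repeated) at 2.81 ± 0.05. Drought and ABA genes split 8 and 8 of 22 (7 and 11), with RD20 at -4.53 ± 0.34, P5CS1 at -2.97 ± 0.17, LTP3 at 2.25 ± 0.29 and KIN1, at a single site, at 6.49 ± 0.14. Flavonoid genes split 3 and 2 of 9 (1 and 3), with the regulator PAP1 at -2.06 ± 0.22. Cell wall genes split 2 and 1 of 11 (0 and 2), clock genes 3 and 1 of 6 (0 and 2), flowering genes 1 and 2 of 8 (0 and 2), described loci 2 and 2 of 7 (1 and 2) and guard cell genes 2 and 0 of 4 (0 and 0). Of 6 reference genes 3 favoured Col (4), while ACT2 lay at -0.06 ± 0.07. The single heat shock gene and 1 of 2 cold and touch genes (2) favoured Col, and none of the 4 salicylate genes (1 toward Col) nor the root gene (toward Col) passed. Under control 4140 genes were called (1807 toward Cvi, 2333 toward Col; 838 and 3500 without centring) and under drought 4035 (1879 and 2156; 773 and 3379). The 2 lists shared 3094 genes, 3089 in the same direction, against 819 for independent lists, and across genes, which are not independent replicates, the ratios correlated at r = 0.945. Both conditions were read at the same sites, so a bias of a site or its mapping can add to this overlap.

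Few ratios changed with drought in F1 plants: 42 genes passed, 28 toward Cvi and 14 toward Col (27 and 16 without centring), 14 by DESeq2. The Cvi share of G4, chlorophyll synthase (chromosome 3, 19215930 to 19219128), went from 13.5% ± 3.09 to 35.4% ± 7.81 (n = 3 each), a log2 change of 1.85 ± 0.28 (adjusted p = 0.00147). That of AT1G12440 (chromosome 1, 4241421 to 4243229) went from 9.39% ± 2.03 to 24.5% ± 6.002 (1.73 ± 0.28), and that of AT4G21660 from 31.1% ± 3.67 to 55.9% ± 5.42 (1.55 ± 0.25). CYCB1;5 (1.65; repeated), AT2G45810 (1.46), PDE345 (1.31), AT1G73530 (1.302), the cellulose synthase CESA5 (1.21), the chaperone Hsp81.4 (1.17; repeated) and AT5G14910 (1.12) followed. With each site weighted alike in both conditions CESA5 turned to -0.27 and Hsp81.4 to -0.06, while AT2G45810 stood at 0.07, PDE345 at 0.26 and AT1G73530 at 0.34. CESA5 turned to -0.40 with rare-allele sites left out and Hsp81.4 to -0.079 at the deepest site. Toward Col changed AT2G35260 (-1.97 ± 0.32), AT5G45590 (-1.57), THI2.2 (-1.38), AIG2 (-1.33), LHW (-1.31) and the metallothionein MT2A (-1.30 ± 0.29), whose Cvi share went from 52.8% ± 7.36 to 31.2% ± 9.11. Of list members, PSAD2 (0.94), LHCB2.2 (0.57; repeated) and UBQ10 (0.83; repeated) were called, but with sites weighted alike PSAD2 stood at 0.06 and LHCB2.2 at 0.21. No list was called by camera (all adjusted p = 0.957). With each site weighted alike in both conditions, the changes were at a median of 0.482 of those of summed reads in the 41 genes with several sites, and 5 turned sign. Toward Col, AT2G35260 stood at -0.998, THI2.2 at -0.65 and AIG2 at -0.65. The ratio stayed at 0.8 or more in 9 of them, among them G4 (0.964), AT1G12440 (1.099), AT4G21660 (0.855), MT2A (0.867) and, chosen after their values were seen, TOM20-2 (0.891), GOX1 (1.05) and AT3G43980 (1.29). Leaving out F1 drought plant 3 left 9 calls and control plant 2 left 11, against 67 without drought plant 2. Of 22 named genes G4, AT4G21660, AT2G35260, at 0.482 of its size with sites weighted alike, and Hsp81.4, whose direction turned at other weights of its sites, stayed called throughout. AT1G12440 lost the call without drought plant 3, GOX1 without that or control plant 2, and TOM20-2, MT2A and AT3G43980 without any of these or control plant 3. In all 17 lost it without drought plant 3, 16 without control plant 2, 9 without drought plant 1 (MT2A among them), 8 without control plant 3, 6 without control plant 1 and 2 without drought plant 2 (AT3G43980 among them).

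In the pools the same ratio compares the parents. Under control 3661 genes differed, 1544 higher in Cvi and 2117 higher in Col (1080 and 2555 without centring), and under drought 3897, 1767 and 2130 (1355 and 2449). The leading genes were AT1G67105 at 5.22 ± 0.22, FBA7 at 3.59 ± 0.14, AT1G76955 at 3.44 ± 0.25, RAN2 at 3.31 ± 0.17 and AT1G52000 at 3.30 ± 0.14 toward Cvi. Toward Col lay AT4G13495 at -6.07 ± 0.15, ESM1 at -6.02 ± 0.12 (repeated), AT5G03350 at -5.28 ± 0.20, MT1B at -4.92 ± 0.20 (repeated) and LIL3:1 at -4.72 ± 0.18 (n = 2 pools). Of the flavonoid genes 6 of 9 were higher in Col, among them PAP1 (-4.73 ± 0.41), LDOX (-4.19 ± 0.25), UGT79B1 (-3.61 ± 0.30) and TT19 (-3.60 ± 0.18). Of 23 glucosinolate genes 10 were higher in Cvi and 9 in Col (9 and 10 without centring), with MAM3 at 2.61 ± 0.15 and CYP79F1 at 1.53 ± 0.12. Under control 2868 genes were called in pools and F1 plants, 2854 in the same direction (751 for independent lists; r = 0.933 across genes), and under drought 2786, 2765 in the same direction (769; r = 0.922). Pools and F1 plants were read at the same sites, so a bias of a site or its mapping recurs in both. The overlap therefore cannot separate shared allele differences from shared bias. The parental ratio changed with drought in 4 genes, 3 toward Cvi and 1 toward Col. At an unadjusted p under 0.05 there were 503, no more than chance alone would give among all tested genes. The Cvi share of AT3G01490, a protein kinase gene, went from 12.2% ± 3.95 to 37.4% ± 2.46, and that of ELIP2, a light stress protein, from 44.9% ± 6.34 to 72.1% ± 9.17. That of BGLU18, a beta-glucosidase that releases ABA, went from 70.3% ± 2.26 to 81.3% ± 1.36, and that of AT3G56360 from 36.0% ± 2.53 to 19.1% ± 0.997 (n = 2 each). At the deepest site of AT3G01490 the Cvi share over all pool libraries was 1.73%, far below the shares summed over its sites. In F1 plants the change of its ratio fell from 1.01 to 0.11 with sites weighted alike, a check not made for the pools. The count of 3661 fell to 2329 without control pool 1, with every named gene still called. The change of the parental ratio was called in 1 gene without control pool 1 and in 38 without drought pool 3, and only AT3G01490 stayed called throughout. There 3 genes lost the call without control pool 1, 2 without drought pool 4 and 1 without control pool 2.

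**Figure D3:**
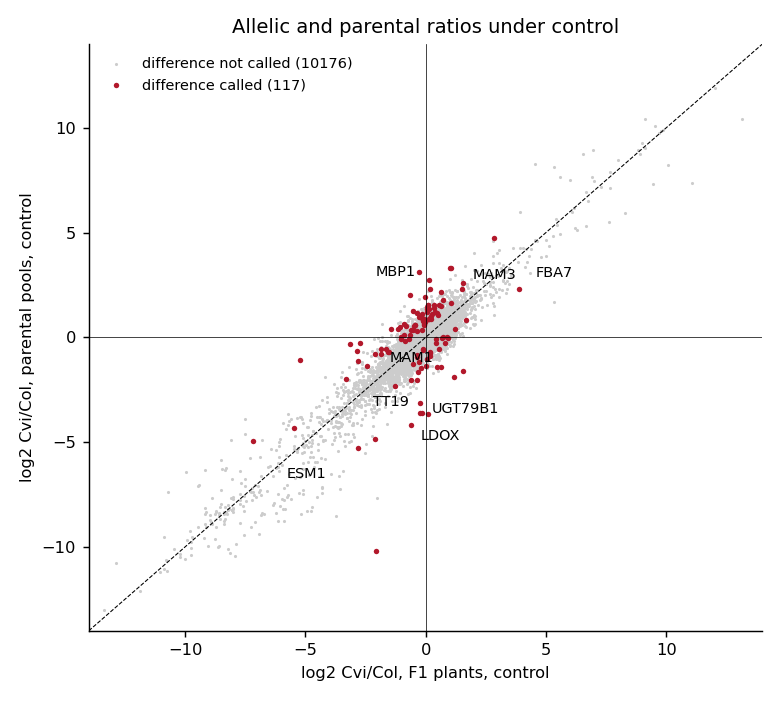
Log2 Cvi/Col of each gene in F1 plants (x axis, n = 3) and in parental pools (y axis, n = 2) under control; the dashed line marks equal ratios. The difference was called in 117 genes; LDOX, TT19 and UGT79B1 lie below the line, at -3.60 to -3.37 in pools minus F1, and MBP1 (2.60), MAM1 and MAM3 above it.

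The difference between the parental and the F1 ratio sets the balance between parents beside the balance of the same alleles within a cell. In 3 anthocyanin genes most reads came from Col in the pools, and the alleles were closer to equal in F1. The Cvi share of LDOX was 4.51% ± 1.60 in control pools and 35.1% ± 4.14 in F1 (log2 difference -3.60 ± 0.39). That of TT19 (chromosome 5, 5658416 to 5659661) was 6.94% ± 0.483 and 41.7% ± 2.71 (-3.37 ± 0.24), and that of UGT79B1 (chromosome 5, 21936746 to 21938396) 6.69% ± 1.54 and 42.7% ± 5.25 (-3.47 ± 0.49; n = 2 pools and 3 F1 plants). At the deepest coding site of each gene, named by the Col base, the chromosome position and the Cvi base, the Cvi shares over all pool and all F1 libraries were 7.0% and 39.3% for LDOX (T12005591G), 6.67% and 41.5% for TT19 (C5658654A) and 6.53% and 39.0% for UGT79B1 (C21938296G). CHS, the entry enzyme of the pathway, differed by -0.86 ± 0.17. Of the 9 flavonoid genes 4 shifted toward Col in the pools relative to F1 and none toward Cvi (7 adjusted over the list alone), with a camera adjusted p of 1.30e-14 (adjusted p = 0.00178 with an estimated correlation, 9.16e-06 by fry). Under drought 5 of 9 did (5 adjusted over the list alone; camera adjusted p = 1.52e-11, adjusted p = 0.00351 with an estimated correlation), with TT19 at -4.31, LDOX at -3.78, UGT79B1 at -3.75, F3PH at -3.33 and CHS at -0.87.

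Of 23 glucosinolate genes, a list that camera called in both conditions but not with an estimated correlation, in 6 the Cvi share was higher in pools than in F1 and in 1 lower (10 and 4 adjusted over the list alone), with a camera adjusted p of 0.000188 (adjusted p = 0.207 with an estimated correlation, 0.0121 by fry). The Cvi share of MAM1 was 38.1% ± 3.22 in pools and 18.8% ± 2.92 in F1 (1.298 ± 0.14). That of MAM3 was 84.7% ± 0.628 and 71.1% ± 2.95 (1.04 ± 0.19), and that of CYP79F1 72.3% ± 1.68 and 46.8% ± 1.90 (1.45 ± 0.16). MYB29 (0.92), CYP83A1 (0.74) and SUR1 (0.70) shifted likewise, and CYP83B1, of indole glucosinolate synthesis, shifted by -0.90. Under drought 9 of 23 shifted toward Cvi and none toward Col (14 and 2 adjusted over the list alone; camera adjusted p = 7.35e-08, adjusted p = 0.0980 with an estimated correlation, 0.00174 by fry). The values were MAM3 at 1.72, CYP79F1 at 1.52, MYB34 at 1.43, MAM1 at 1.42, SOT18 at 1.26, SUR1 at 1.09 and MYB28 at 0.79. Of 27 photosynthesis genes 2 were called toward Col under control (1 without centring; 6 adjusted over the list alone; camera adjusted p = 0.00879, adjusted p = 0.0790 with an estimated correlation, so the list lost its call, 0.00446 by fry). Under drought 1 was called toward Col, but without centring 2 toward Cvi and 1 toward Col.

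**Figure D4:**
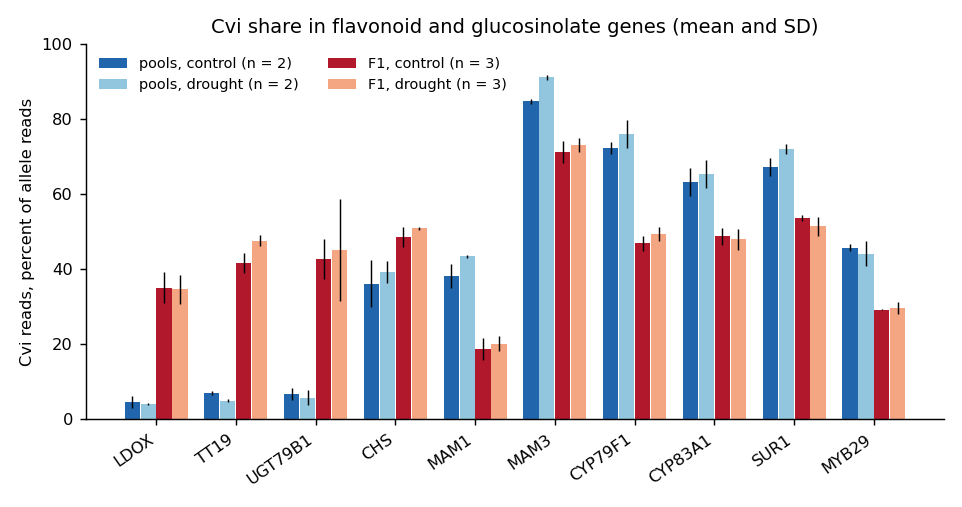
Percent of allele reads from Cvi (y axis) in flavonoid and glucosinolate genes (x axis) in pools and F1 plants under control and drought; bars are means and error bars SD over 2 pools or 3 F1 plants. In LDOX, TT19 and UGT79B1 the pools lie under 7% and F1 plants between 34.6% and 47.6%, while in MAM1, MAM3 and CYP79F1 the pools lie above the F1 plants.

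Under control 117 genes differed between pools and F1 in ratio, 78 toward Cvi and 39 toward Col in pools (114 and 25 without centring), and under drought 231, 146 and 85 (346 and 38); DESeq2 called 56 and 97. Repeated genes made up 5.98% of the control and 10.4% of the drought calls, against 5.48% of all tested genes (called against the remaining tested genes, Fisher's exact test, p = 0.686 and 0.00291, two-sided). Outside the lists the largest shifts toward Cvi under control were MBP1, a myrosinase-binding protein (2.60 ± 0.31; chromosome 1, 19350314 to 19352791), AT5G22460 (2.31), AT1G52000 (2.24), FMO GS-OX2 (2.19), AT3G28220 (2.13), the wax ester synthase WSD1 (1.94), HPL1 (1.90), AT3G28270 (1.77) and CNGC12 (1.68; repeated). Toward Col lay AT4G38932, with 0% Cvi reads in control pools against 15.9% ± 8.41 in F1, AT3G44970 (-3.18) and AT5G35480 (-3.06). Under drought the largest shifts toward Cvi were MBP1 (4.38), AT1G52000 (2.95) and AT3G28220 (2.88). Both conditions shared 70 genes, all in the same direction, against 1.43 for independent lists. The difference itself did not change with drought in any gene by edgeR (616 at an unadjusted p under 0.05, 0 by DESeq2). The control count fell to 48 without control pool 2, 61 without control pool 1 and 66 without F1 control plant 2, and the drought count to 137 without F1 drought plant 3. The change of the difference was called in 15 genes without drought pool 3, in 6 without drought pool 4 or F1 drought plant 2 and in 1 without F1 control plant 1. Of the genes named, AT5G22460, HPL1, MAM3, CYP83A1 and SUR1 lost the control call without control pool 2, and WSD1, CYP83B1 and CHS without control pool 1. Leaving out F1 control plant 2 ended it for HPL1, CYP83A1, SUR1 and CYP83B1, and plant 1 for CYP83A1 and SUR1. The drought call was lost by MYB28 and CHS without drought pool 3, by MYB28, MYB34 and SOT18 without drought pool 4, by MYB34 and SOT18 without F1 drought plant 1 and by MYB28 without plant 2 or 3, while LDOX, TT19, UGT79B1, MAM1, CYP79F1 and MBP1 kept both.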

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

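The tests of uneven coverage behind the drought changes and behind the genes lower in F1 plants, of other splits of the plants for the drought and ratio changes, of swapped allele labels and of the state of the F1 control plants were chosen only after the result was seen. Effects that differed between groups by a test of the difference itself were the change of the allelic ratio with drought, called in 42 genes in F1 plants and in 4 genes in the pools for the parental ratio, and the difference of the parental from the F1 ratio, called in 117 genes under control and 231 under drought. In a column that the comparisons do not use, reads at sites with a base of neither allele took a share 0.0386 percentage points higher under drought than under control. A single gene, LHB1B2, held 16.6% of these bases under control and 21.0% under drought. For the unequal allelic ratios in F1 plants chance differences between plants are argued against: of 32 ways to swap the allele labels between plants only the real one (1 of 32) gave 5414 calls, and the highest other, with all drought plants swapped, gave 42. A bias shared by all plants is left open by this. For the gene lists that moved with drought the 10 splits of the 6 F1 plants, the real one included, are too few for a share under 0.05; the real split (1 of 10) called 5 lists and the highest other 4.

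Drought changes seen at polymorphic sites in F1 plants were often not seen over the whole gene, with 167 of 555 calls shared. Reads shared with near-identical copies in the reference genome are argued against, since the share of repeated genes among calls from site reads alone was 0.988 times that of all tested genes. Coverage that varies along transcripts from plant to plant stays open: in 3298 genes, sites at least 300 bp apart differed in their drought change by a median of 0.586 log2 in F1 plants and 0.244 in pools, a ratio of 2.40 (2.33 with 2 libraries per group), but the spread of the pools may be technical, so this ratio does not decide. The 10 splits of the plants, the real one included, are too few for a share under 0.05; the real split (1 of 10) called 555 genes and the highest other 0 in site reads, and 659 and 1 in all reads. A drought effect on which part of a transcript is made, which may differ between plants and pools, was not tested and stays open.

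Changes of the allelic ratio with drought in F1 plants shrank to a median of 0.482 of their size when each site was weighted alike in both conditions, so uneven coverage along transcripts could account for much of them, though not for the 9 genes that kept 0.8 or more. Repeated genes were 4.35 times as frequent among the called genes as among all tested genes (10 of 42, 23.8% against 5.48%), so shared reads may account for part. Called genes were tested against the remaining tested genes (Fisher's exact test, p = 6.74e-05, two-sided). Of the called genes 40.5% had no repeated 30-base word in the reference genome, against 60.5% of all tested genes. For these no shared reads were seen by this measure. Copies that differ by a few bases, or that only Cvi carries, could escape it, so it does not decide for them. The 10 splits, the real one included, are too few for a share under 0.05; the real split (1 of 10) called 42 genes and the highest other 4. A response of 1 allele to drought stays open, with G4 and AT4G21660 as the genes below the limit for repeats that held with sites weighted alike and with any library left out, while AT1G12440, MT2A, TOM20-2, GOX1 and AT3G43980 held with sites weighted alike but each lost the call without F1 drought plant 3.

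Genes lower in F1 plants than in pools under control included ACD6 and 3 anthocyanin genes. In 19 of the 28 genes the F1 mean lay below both parental levels estimated from the pools. ACD6 was 1 of them, at 278 CPM in F1 against 1255 for Col and 929 for Cvi. LDOX, TT19 and UGT79B1 lay between the parental levels, nearer to the lower one of Cvi. For LDOX this was 13.7 CPM in F1 against 101 for Col and 4.76 for Cvi. Uneven coverage is argued against, since 92.9% of the 28 were also called lower from all reads. More Col than Cvi cDNA in the pools is argued against too: the 1333 other genes called higher in the Col parent by a log2 of at least 1 had a median F1 minus pool change of 0.0141, not a fall. The state of the 3 F1 control plants, rather than of hybrids, cannot be told apart from an effect of the cross: the plant of the other cross direction lay nearer to the pools in 20 of the 28 genes, such as ACD6 (1092 CPM in pools, 278 in F1 and 1334 in that plant), yet 18 of the 28 were also lower in the F1 drought plants, and it is a single plant. Nearer to the F1 plants were 8 genes, among them LDOX, TT19 and UGT79B1, and for these a property of hybrids stays open as a hypothesis.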

How the results depend on the processing

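The use of all reads per gene and of the deposited allele reads per gene was chosen only after the data were seen; the other alternatives were fixed before. For the named values, 3633 alternative values were computed: 3058 kept direction and side of the threshold, 561 kept the direction but no longer passed, 5 newly passed and 9 reversed. Reversed were PSBP1 with drought in all reads (-0.34) and PIP2;2 likewise (-0.52); PR1 in F1 against pools with the other cross direction joined (1.56); KIN2 (1.202 under control, 1.05 over both conditions), RPP5 (0.27) and the CESA5 ratio change (-0.40) with sites of a rare allele left out; and RPP5 (0.18) and the Hsp81.4 ratio change (-0.079) at the deepest site. For these the cause was not tested, beyond the fewer sites used. DESeq2 size factors and the deposited allele reads per gene moved no count by over 1.5 times. Genes below a minimum, or not measured in an alternative, have no value there.

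Counts that moved by over 1.5 times are given in the order drought in F1, drought in pools, their difference, F1 against pools under control and under drought, F1 ratio under control, under drought and over both, its change, parental ratio under control and under drought, its change, and parental minus F1 ratio under control, under drought and its change. The main counts are 555, 4, 0, 33, 27, 4140, 4035, 5414, 42, 3661, 3897, 4, 117, 231 and 0. With DESeq2 drought in pools gave 23, the difference 22, F1 against pools 68 and 95, the F1 ratio 2688 and 2524 and its change 14, the parental ratio 2243 and 2343 and its change 2, and parental minus F1 ratio 56 and 97. At the deepest site drought in pools gave 0, F1 against pools 8 and 2, the F1 ratio 2390, 2257 and 3030 and its change 23, the parental ratio 2229 and 2280, and parental minus F1 ratio 56, 105 and 1. With a mean of at least 100 drought in pools gave 0, F1 against pools 8 and 9, the F1 ratio 2441, 2437 and 3032, and the parental ratio 2271 and 2351, from fewer genes tested. Without a minimum drought gave 1058 in F1 and 32 in pools and the difference 67, F1 against pools 146 and 212, the F1 ratio change 101, the parental change 25, and parental minus F1 ratio 204 and its change 31. With only the compared groups in the model drought gave 203 in F1 and 30 in pools, F1 against pools 58 and 5, and the parental change 1. Without centring the parental change gave 8, and parental minus F1 ratio 384 under drought and 1 for its change. With the other cross direction joined, drought in F1 gave 327 and F1 against pools under control 7. All reads gave 17 for drought in pools and 114 and 82 for F1 against pools. Drought in pools gave 0 with sites at least 100 bp apart and 2 with rare-allele sites left out or with all sites in the gene span. Of the 5 lists called with drought in F1, 1 stayed called with an estimated correlation. The cause of these moves was not tested where none is named.

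With 1 library left out in turn, the lowest and highest counts were 147 to 879 for drought in F1 (139 to 733 in all reads), 0 to 2 in pools (0 to 12), 0 to 53 for the difference (0 to 13), 4 to 21 and 4 to 221 for F1 against pools under control and drought (32 to 105 and 24 to 375), 3133 to 3463, 3102 to 3284 and 4817 to 5011 for the F1 ratio and 9 to 67 for its change. They were 2329 to 2441 and 2731 to 2810 for the parental ratio, 1 to 38 for its change, 48 to 110 and 137 to 230 for parental minus F1 ratio, 0 to 15 for its change, 4 to 5 for the lists with drought and 0 to 0 for the lists with the ratio change. Where a group was left with 1 library, that library is assumed to vary like those of the other groups.

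With the replicate number as a block, drought in F1 gave 194 calls, F1 against pools under control 226 (91 higher, 135 lower), the F1 ratio change 46 and parental minus F1 ratio under control 183, with 5 lists called for drought in F1 and 0 for the ratio change. Nothing states that the numbers pair the libraries, and the values do not settle it. Deviations of libraries with the same number correlated at -0.05 to 0.05. Between F1 control and drought plants, numbers 2 and 3 correlated best with their own number in levels (0.045 and 0.041), but number 1 did not, and none did in ratios. F1 control plants and control pools share only 2 numbers, so their 2 correlations are equal by construction and cannot show pairing.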

Other observations

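The counts of near-silent alleles, the comparison of single plants, the values by site density and along chromosomes and the test of bases of neither allele were chosen only after the data were seen. Some alleles gave almost no reads in any library. Of 8579 genes examined, 45 had under 1% Cvi reads in every library and 11 had under 1% Col reads, with 4 and 5 of them repeated. In F1 plants under control the Cvi allele gave 0% of reads at 50 sites of AT1G63880, 30 sites of AT4G07825 and 21 sites of AT4G16190, and the Cvi share was 100% at 33 sites of AT2G13750 and 12 sites of AT5G45095. For several genes of primary metabolism, among them the carbonic anhydrase CA1, the malate dehydrogenase PMDH2, triose phosphate isomerase TPI, the methionine cycle genes SAM1 and SAHH2 and NADP-ME2, the call rests on 1 site each, so a wrongly listed base and a silent allele cannot be distinguished by these values. EXPA5, an expansin, had 0% Cvi reads at its single site under control. DOG1, a seed dormancy gene first described from Cvi, had 4.88% ± 3.22 Cvi reads in F1 plants under control (SD, n = 3) and 5.0% in control pools.

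The plant of the other cross direction resembled the F1 control plants in its allelic ratios. Across 10293 genes, which are not independent replicates, its ratios correlated with theirs at r = 0.857 to 0.882, against 0.860 to 0.890 among the 3 F1 control plants. Of 6186 well covered genes, 36 to 56 had a ratio over a log2 of 1 away from both of a pair of F1 control plants in the same direction, against 32 to 94 when a F1 control plant took its place. In 18 genes the ratio lay that far from all 3; among them WAK2 was at -0.14 against a mean of -1.60, CNGC12 at -0.71 against -2.80 (repeated), AIG2 at 0.33 against 1.92 and AT5G03350 at -4.86 against -2.73. With 1 plant these values have no replicate check.

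Genes with many neighbouring sites had lower Cvi shares. Without centring, the median log2 Cvi/Col in F1 plants was -0.13 in the 3208 genes with 0 other sites within 50 bp and -0.51 in the 145 genes with over 4, and in pools -0.01 and -0.37. Along the chromosomes the centred medians in windows of 2000000 bases lay between -0.29 and 0.19 in the plant of the other cross direction. Its lowest window (chromosome 3 from 14000001, 41 genes) stood at -0.173 in F1 control and -0.265 in F1 drought plants. Its highest (chromosome 5 from 10000001, 21 genes) stood at 0.014 and 0.085 in them and at 0.121 and 0.165 in control and drought pools. Bases of neither allele took 0.540% ± 0.0206 of reads at sites under drought (n = 5) and 0.502% ± 0.0102 under control (n = 6). A two-sided exact permutation test gave p = 0.00216 over 462 splits, the only measure tested in this way. That is the lowest p these splits can give. They also mix F1 plants with pools, whose libraries may be technical replicates. The difference between drought and control was 0.0379 percentage points within F1 plants and 0.0378 within pools. It need not be general, since a single gene, LHB1B2, held 16.6% of these bases under control and 21.0% under drought. AT1G67050 went from 2.62% to 3.88%, while AT1G07920 went the other way, from 8.67% to 6.64%.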
